A study of Homo sapiens with 10 samples.

How the data were processed

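ATAC-seq, in which the Tn5 transposase cuts accessible DNA and adds sequencing adapters to it, was performed on MDA-MB-231 cells. MDA-MB-231 is an established human line of triple-negative breast cancer. The 10 libraries fall into 2 groups of 5 by the genotype in the labels, ARID1A knockout and control, with replicate numbers 1 to 5 in each. Per the labels' protocols, lysed cells were tagmented after a published ATAC-seq protocol with small changes, and the fragments were amplified by PCR. The labels do not say whether the replicates came from separate cultures.

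Per the submitters' processing notes, reads were aligned with Bowtie2 2.3.5.1 and peaks were called with MACS2 2.2.6 on the human build hg38. The threshold of the peak caller, the handling of duplicate and mitochondrial reads, any shift of reads for the Tn5 cut, the merging of peaks across libraries and the annotation release are not given in the sources used here. These steps set the number, length and edges of the peaks, and so every count reported.

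The deposited file analysed here is 1 list of 161934 peaks for the whole series. Per the file headers, its 17 columns give the position and length of each peak in bases, an annotation class, and the nearest transcript with its distance in bases. The list has 0 columns with a value per library and no peak height, fold or p-value. The depth per library is therefore unknown here, and no difference between knockout and control was computed. The tests fixed before the data were examined needed counts per library and were not run. The gene lists come from that plan. The tests, the windows and the rule for named genes as used here were chosen after the contents of the list were known. Some rows may be outside the list analysed here, so a missing peak means only that this list holds none.

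In all 161934 rows the length equalled end minus start plus 1. The distance to the nearest transcript start was recomputed, and 100% of rows gave the listed value. Promoter peaks are those the list annotates as such, which lie within 3000 bases of a transcript start. Shares of peaks carry Wilson 95% intervals. These cover only counting error over peaks, which are not replicates.

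Gene symbols were taken from a RefSeq gene table of the same build, in which 19821 protein-coding genes lie on chromosomes 1 to 22 and X. An Ensembl identifier was paired with a symbol where each was the best match of the other by position and their overlap was at least 0.8 of their union, which gave 12776 genes (64.5%). The table gives no strand. Strand came from the list's transcripts, either of the gene matched at an overlap of at least 0.5 of the union or of transcripts within 500 bases of the gene's boundary. Both ways gave a strand for 12347 genes and the same strand for 12305 (99.7%). For 924 genes strand rested on the boundary transcripts alone. These can belong to an overlapping gene, so the strand and start state of some of these genes, and with them the list counts, may be wrong. A gene has a start peak where a peak lies within 1000 bases of its outermost 5' boundary. Where strand was unknown, the state was set only if both ends or neither had a peak, and was left undetermined if a peak lay at an annotated start inside the gene. The rule on starts inside the gene was added after the list results had been seen. The first definition is kept as an alternative.

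For each of 19 gene lists (489 genes, all found, 1 through a synonym), the share with a start peak was compared with all other protein-coding genes by a two-sided Fisher's exact test across genes, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. Shares carry exact 95% intervals. Genes are not independent replicates, so these tests describe this list and carry no replicate error. Peaks in the gene body are all peaks that overlap the gene, start peaks included. Their median number per list was set against 10000 random lists drawn from the 200 genes nearest in length to each member. A position drawn at random 100000 times gave the chance level.

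The lookup of peaks was tested on 1000 simulated intervals, of which 1000 were counted as by brute force. The list test was tested on 200 simulations over 19821 genes. A planted share of 98% was found in 92% of simulations for the SWI/SNF list and in 2% for the 15 housekeeping genes. The adjustment is milder where more lists pass. In the data 9 lists passed, more than were planted, so the 2% is not the power of the reported test. A planted share of 30% was found in 92.5% for the leukocyte and 76% for the endothelial list. Lists left at the base share passed in 0.433%.

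Genes named in the text are ARID1A and ARID1B, then up to 3 members of each list with the longest start peak and up to 5 without a start peak, and the 8 paired genes with the most peaks. A gene that the rule takes is not reported here. Other genes named were chosen after their values were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were other windows, definitions of a start, subsets of peaks and reference genes.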

Results

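Accessible chromatin was mapped by ATAC-seq in MDA-MB-231 cells, a triple-negative breast cancer line, with 5 ARID1A knockout and 5 control libraries. ARID1A is a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. The design addresses how loss of ARID1A changes accessibility. The peak list analysed here covers the whole series and holds no value per library. Which peaks differ between knockout and control, and by how much, was therefore not measured here. What follows describes where the 161934 peaks lie and which genes they mark. It has no replicate error.

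The ARID1A gene itself (ENSG00000117713, hg38 chromosome 1, 26696015 to 26782104, plus strand) held a start peak at 26695365 to 26696153. With 3000 bases on either side, 11 peaks lay at the locus. Of these, 7 were annotated as promoter, 4 as intron and 0 as exon. The promoter class takes every peak within 3000 bases of any annotated transcript start, also inside the gene. The longest, 1758 bases at 26771331 to 26773088, covered another annotated transcript start of the gene. The list ties no peak to a library or genotype, so these peaks do not check the knockout label of any library. ARID1B, the paralog that can take the place of ARID1A in the complex (chromosome 6, 156776026 to 157210779), had a start peak at 156776993 to 156777683 and 29 peaks in its body.

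Peaks covered 105 Mb, with a median length of 539 bases (interquartile range 346 to 843, range 121 to 4288). Introns held 55143 peaks (34.1%), promoters 49151 (30.4%, 95% Wilson interval 30.1 to 30.6) and distal intergenic sequence 47897 (29.6%). Exons held 4437 peaks, 3' UTRs 2964, regions just downstream of genes 1990 and 5' UTRs 352. A transcript start lay inside 12.5% of peaks, while 46.0% lay 10000 bases or more from the nearest one. Promoter peaks within 1000 bases of a start were longer than the rest, with a median of 856 bases against 506 for distal intergenic peaks. Of the former 41.1% exceeded 1000 bases, and of the latter 11.2%. The promoter share depends on the definition, and was 19.8% within 1000 bases of a transcript start and 37.8% when counted in bases.

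**Figure D1:**
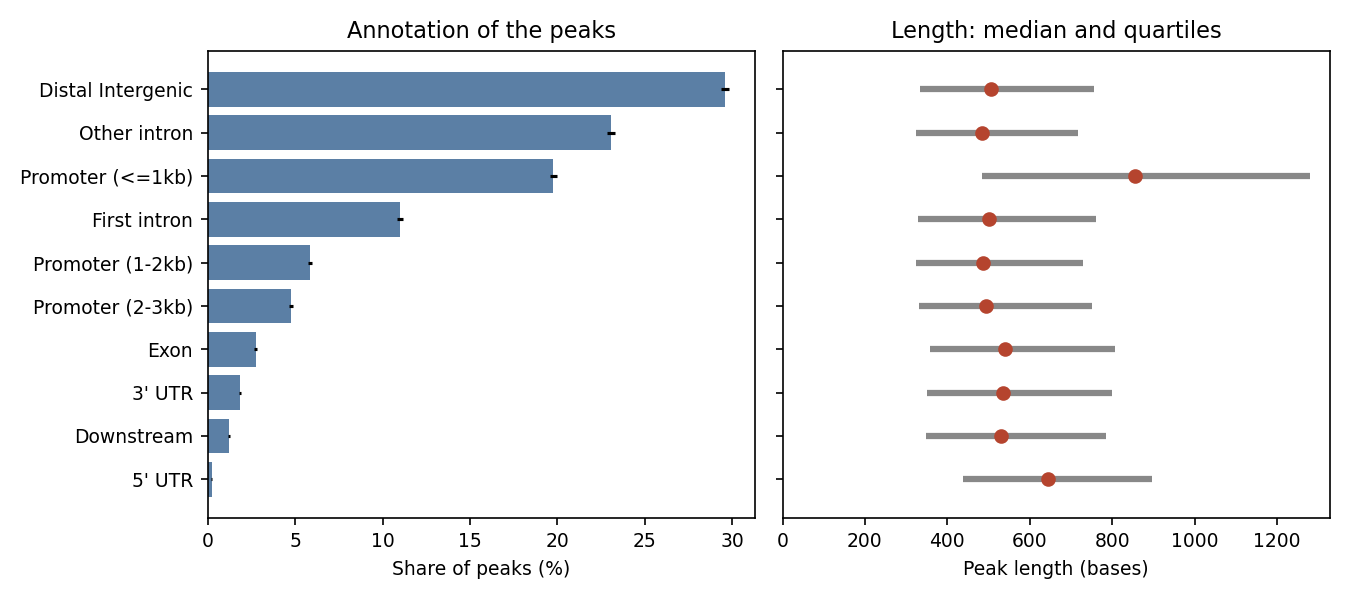
Annotation and length of the 161934 peaks, by class. Left, the share of peaks (%) with Wilson 95% intervals; right, the median length in bases (points) and the interquartile range (lines), which is highest for promoter peaks within 1000 bases of a start (median 856).

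Chromosomes differed in how their peaks related to genes. MDA-MB-231 cells are aneuploid and copy number was not measured. Its part in the densities and counts below cannot be told apart from that of chromatin. Chromosome 19, the most gene-dense, held 3.72 peaks per protein-coding gene, and 57.3% of its peaks were in promoters (interval 55.9 to 58.6). Chromosome 13 held 17.1 peaks per gene, and 18.1% were in promoters (17.2 to 19.2). Within 1000 bases of a transcript start, the shares were 39.7% on chromosome 19 and 11.2% on chromosome 13. By length, peaks were densest on chromosomes 19 and 20 (89.9 and 86.9 per Mb) and sparsest on chromosomes X and 18 (20.3 and 29.8 per Mb). Among windows of 1 Mb, the median held 51 peaks. The densest windows held 212 each and lay at the end of chromosome 13 (113000001 to 114000000, with MCF2L, LAMP1, CUL4A and GAS6) and on chromosome 20 (62000001 to 63000000, with LAMA5, GATA5 and COL9A3).

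Of 18193 protein-coding genes whose state was determined, 13225 (72.7%) had a start peak, against 13.5% of random positions. Another 1628 genes were undetermined, and 2299 genes had no peak in the body or within 1000 bases of either end. The share rose to 81.8% with a window of 3000 bases, where random positions reached 29.1%.

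Genes of the SWI/SNF complex had start peaks throughout. All 26 of 26 subunit genes had one (exact 95% interval 86.8 to 100%), against 72.7% of other genes (Fisher's exact test, two-sided, adjusted exact p = 0.00324). The longest were at SMARCA2, an ATPase of the complex (3366 bases, chromosome 9, 2014703 to 2018068), SMARCD2 (2234 bases) and BICRAL (2190 bases). The call ended with a window of 3000 bases, where 26 of 26 had a peak and the adjusted exact p was 0.0576. The reference holds all other protein-coding genes, expressed or not, and expression was not measured. All 15 housekeeping genes also had a start peak. Passing above this reference therefore does not set a list apart from broadly expressed genes, which holds for every list that did so.

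The list of PI3K, receptor tyrosine kinase and MAPK genes and the interferon list also passed above other genes. Of the former, 36 of 37 had a start peak (97.3%, interval 85.8 to 99.9, adjusted exact p = 0.00286). Examples were EGFR, the epidermal growth factor receptor, with a start peak of 2491 bases at chromosome 7, 55018351 to 55020841, and 36 peaks in its body, and the pathway inhibitors SPRY1 (3234 bases) and SPRED2 (2651 bases). FGFR2 had none at its outermost start. Of the interferon response and antigen presentation genes, 33 of 34 had a start peak (97.1%, adjusted exact p = 0.00324). They included TAP1, a peptide transporter (2160 bases), IFIT2 (1725 bases) and NLRC5, an activator of MHC class I genes (1666 bases). CIITA, the activator of MHC class II genes, had none at its outermost start. With the window of 3000 bases the interferon list no longer passed (adjusted exact p = 0.0591).

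Growth and stress genes followed. Start peaks were found at 32 of 34 cell cycle and replication genes (94.1%, adjusted exact p = 0.012), among them CCNE2 (2496 bases), CDT1 (1924 bases) and PLK1 (1833 bases). The exceptions, the cell cycle inhibitors CDKN2A and CDKN2B, had no peak in this list. Both lie in the stretch of 4.18 Mb on chromosome 9 without any peak, described below. Whether the DNA there is lost or its chromatin closed was not settled, so these genes do not show closed chromatin. Of the DNA damage response genes 28 of 29 had one (96.6%, adjusted exact p = 0.012), with 3153 bases at the outermost start of BRCA1 and 1727 bases at MSH6. The BRCA1 peak ran past the gene's boundary at 43170327, to 43172436, and which gene it marks was not tested. The exception in this list was CHEK1, whose strand, taken from boundary transcripts alone, is opposite to its known orientation. A peak lay at its other end, so its state is in doubt. The apoptosis list and the glutathione and redox list each had 24 of 25 (96%, adjusted exact p = 0.0159). They included BID (2711 bases), BAD (2392 bases), TXN (2491 bases) and NFE2L2, the regulator of the oxidative stress response (2100 bases). HRK had none at its outermost start but a peak at another annotated start, and GPX2 had none at either. All 15 housekeeping genes had one (adjusted exact p = 0.0343), the longest at GAPDH (3148 bases) and ACTB (3065 bases). None of these 5 lists passed with the window of 3000 bases. The cell cycle, DNA damage, glutathione and housekeeping lists also did not pass when any annotated start was accepted.

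Leukocyte markers were the list that passed the test below other genes, with 9 of 20 (45%, interval 23.1 to 68.5, adjusted exact p = 0.0233). CD3E, CD3G, CD4, CD2 and CD79A had no start peak, and CD8A, CD14 and CORO1A had one. This call was lost with the window of 3000 bases, where 14 of 19 had a peak (adjusted exact p = 0.469), and when undetermined genes were counted as having none (adjusted exact p = 0.0584). Endothelial markers had 7 of 13 (53.8%, adjusted exact p = 0.191). ESAM, ENG and ROBO4 had a start peak. CDH5, TEK, ERG, TIE1 and EMCN had none at their outermost start, though CDH5 and TIE1 had a peak at another annotated start.

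**Figure D2:**
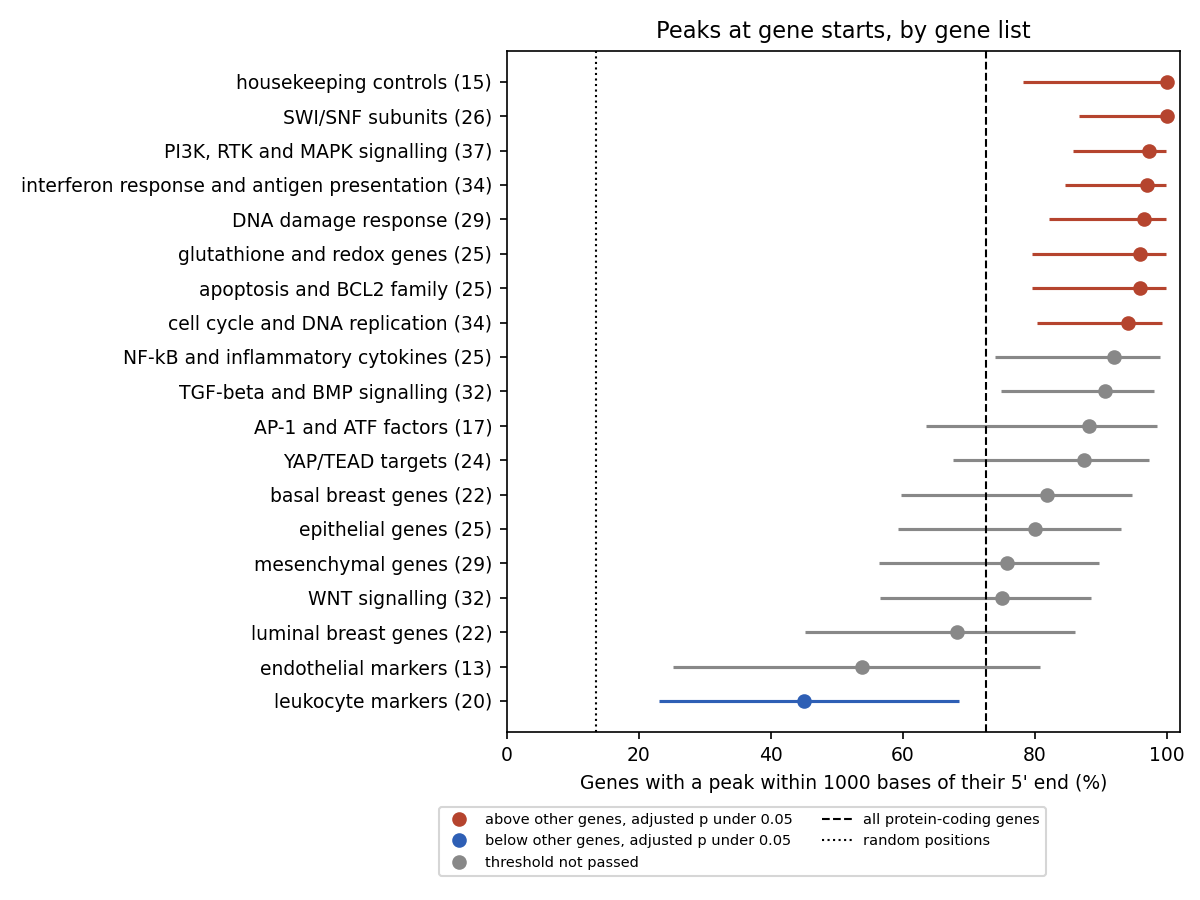
Share of genes (%) with a peak within 1000 bases of the 5' end, for 19 gene lists with the number of genes in brackets. Points are shares and lines exact 95% intervals; red and blue mark lists above (8) and below (1) other genes at an adjusted p under 0.05, the dashed line is all protein-coding genes (72.7%) and the dotted line random positions (13.5%).

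Lists of breast cell identity did not pass the test. Basal genes had 18 of 22 (81.8%, adjusted exact p = 0.6), with long start peaks at FOXC1 (2819 bases), EGFR and SOX9 (2268 bases), and none at the keratins KRT14, KRT6A and KRT6B or at the outermost start of TP63. Luminal genes had 15 of 22 (68.2%, adjusted exact p = 0.71). FOXA1 (1890 bases), PGR (2212 bases) and MYB (2951 bases) had one. ESR1, the estrogen receptor, had none at its outermost start but 28 peaks in its body, and NAT1, AGR2 and AGR3 also had no start peak. Epithelial genes had 20 of 25 (80%, adjusted exact p = 0.6). OVOL2, PKP3 and ESRP2 had one, and CDH1, the gene of E-cadherin, had none at its outermost start but 8 peaks in its body. GRHL3, RAB25, ST14 and TJP3 also had no start peak. Mesenchymal genes had 22 of 29 (75.9%, adjusted exact p = 0.845), with start peaks at MMP14 (2761 bases), LOX and LOXL2 and none at CDH2, COL3A1, MMP2, SPARC or POSTN. For many of these genes, CDH1, ESR1, TP63 and CDH2 among them, a peak lay at another annotated start.

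The remaining lists also stayed short of the threshold. AP-1 and ATF factors had 15 of 17 (88.2%, adjusted exact p = 0.247), with FOS (2599 bases), BATF3 (2525 bases) and JUN (2504 bases) leading. ATF3 and MAFG had none at their outermost start. The list of YAP/TEAD targets, which also holds the TEAD factors themselves, had 21 of 24 (87.5%, adjusted exact p = 0.18). These included the factor TEAD4, and ARHGEF17 and GADD45B. AMOTL1 and DLC1 had none at their outermost start, and FOXF2 had no peak in this list. NF-kB and inflammatory genes had 23 of 25 (92%, adjusted exact p = 0.0688), with ICAM1 (2428 bases), NFKB2 and CSF3, and no start peak at TNF or LIF. TGF-beta and BMP genes had 29 of 32 (90.6%, adjusted exact p = 0.0507), including NOG, SMAD2 and SKIL. TGFBR3, BMP7 and GREM1 had none at their outermost start. WNT genes had 24 of 32 (75%, adjusted exact p = 0.845), including WNT9A, FZD7 and AXIN2. WNT3A, WNT10A, TCF7, DKK3 and SFRP1 had none at their outermost start, though WNT10A, TCF7 and DKK3 had a peak at another annotated start. The NF-kB and TGF-beta lists passed under the first definition of a start peak, with adjusted exact p of 0.0423 and 0.0323. That definition gave 11 lists past the threshold, 10 higher and 1 lower, against 9 as reported, 8 higher and 1 lower. It was replaced after its results had been seen.

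Peaks inside gene bodies gave another order. The median member of the basal list held 5 peaks, at a percentile of 99.7% among length-matched random lists with ties split evenly. That of the mesenchymal list also held 5 (99.5%). The median AP-1 gene held 3 (99.5%), and the median NF-kB gene 1.5 (97.7%). For the SWI/SNF list the median of 4.5 stood at 71.3%. These percentiles describe the list and were not tested. The gene with most peaks was TENM2, with 140 over 1285129 bases. Among genes paired with an Ensembl identifier, the highest counts were at PTPRN2 (130 peaks over 1049 kb), NALF1 (109 over 704 kb), RYR2 (100) and CDH13 (99). RPS6KA2 held 94 within 453 kb. Per length, among genes of at least 20000 bases, HIF1A, the hypoxia-inducible transcription factor, held 24 peaks or 4.55 per 10000 bases, and the activin gene INHBA 7 or 3.45 per 10000. TENM2, HIF1A and INHBA were chosen after their values were seen. Body counts include peaks of overlapping genes and start peaks that reach into the gene, and may vary with copy number, which was not measured. At FOS and JUN the 1 body peak was the start peak. The percentiles are therefore not independent of the start peaks.

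On chromosome 9, no peak in the list lay between 20732855 and 24912766, a stretch of 4.18 Mb. It begins inside FOCAD and holds 24 protein-coding genes, of which 16 are type I interferon genes and 8 are others, including MTAP, KLHL9, CDKN2A and CDKN2B. The 2 Mb beyond its edges held 37 and 23 peaks per Mb. A shorter stretch without peaks, 1.7 Mb from 16443055 to 18143126, lay on the same arm and held CNTLN and SH3GL2.

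**Figure D3:**
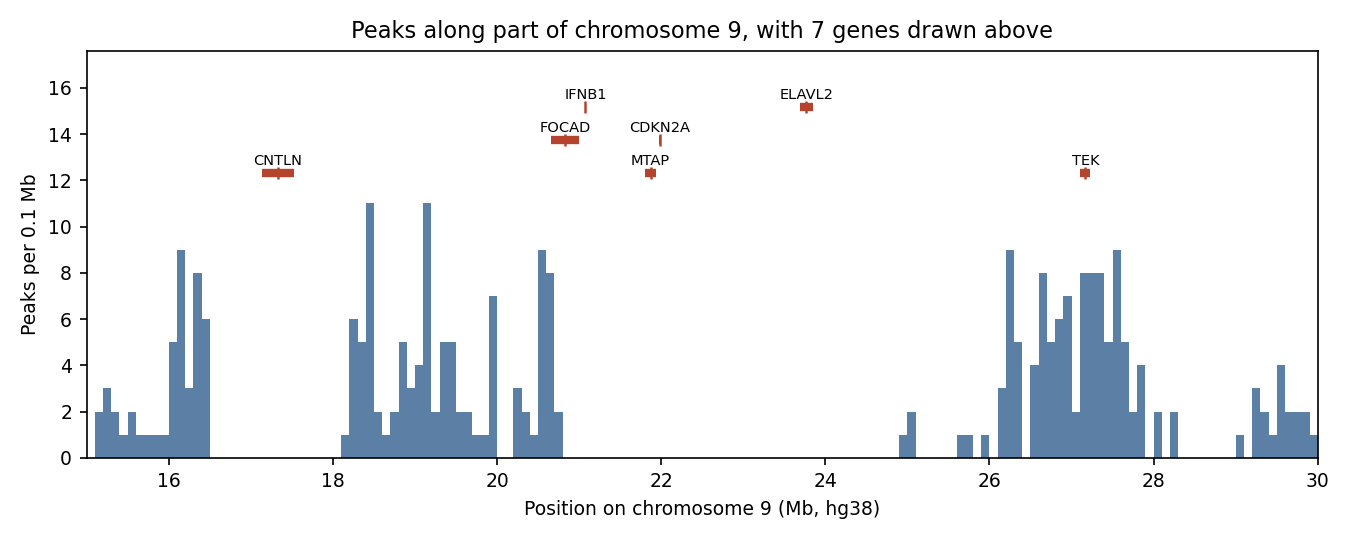
Number of peaks per 0.1 Mb along hg38 chromosome 9 from 15 to 30 Mb (bars), with 7 genes drawn above as horizontal bars and ticks at their middle. The empty stretch of 4.18 Mb runs from within FOCAD past ELAVL2.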

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

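The tests in this part were chosen after the result was seen. Of the peaks, 11 lay on the mitochondrial genome and 70 on 14 unplaced contigs, both outside the chromosomes described. Mitochondrial peaks covered 50.8% of the annotated mitochondrial span, against 3.56% of chromosomes 1 to 22 and X. Any peak there means that reads placed on the mitochondrial genome were kept during peak calling. The comparison of coverage could not have counted against this and adds no evidence for it. A possible explanation of the coverage in terms of the cells was not tested, since no group value was used. The 70 contig peaks, at most 17 on any contig, are given as values.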

How the results depend on the processing

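The alternatives here were chosen after the data were examined, except the promoter definition of 1000 bases. No paired analysis was possible because the list has no value per library. For the same reason the planned changes of normalization, test, filter, threshold, GC content, replicate block and motif window, and leaving out each library, were not run, and the depth limit is unknown. The promoter share, 30.4% as reported, was 19.8% within 1000 bases, 37.2% among peaks of the median length or longer and 37.8% in bases. Genes with a start peak, 72.7% as reported, were 81.8% with 3000 bases, 79.2% at any annotated start, 67.0% with longer peaks only, 74.9% and 66.7% with undetermined genes counted as having or lacking one, and 71.6% under the first definition. Promoter peaks were longer than intron peaks (median 683 against 489 bases), which raises their share among longer peaks and in bases.

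Of 133 list results under 7 alternatives, 105 kept their direction and side of the threshold, 13 lost the call, 9 gained one and 6 turned direction. With 3000 bases the share over all genes rose from 72.7% to 81.8%. The counts for SWI/SNF (26 of 26), interferon (33 of 34), glutathione (24 of 25) and housekeeping genes (15 of 15) did not change. At any annotated start that share rose to 79.2%, with unchanged counts for cell cycle, DNA damage, glutathione and housekeeping genes. These calls were lost as the reference share rose. The cause of the other changes was not tested. With 3000 bases, calls were lost for SWI/SNF (100%, adjusted exact p = 0.0576), interferon (97.1%, 0.0591), cell cycle (94.3%, 0.143), DNA damage (100%, 0.0574), apoptosis (100%, 0.0591), glutathione (96%, 0.143), leukocyte (73.7%, 0.469) and housekeeping genes (100%, 0.155). At any annotated start, calls were lost for cell cycle (94.1%, 0.0692), DNA damage (96.6%, 0.0527), glutathione (96%, 0.0706) and housekeeping genes (100%, 0.0766), and TGF-beta gained one (96.9%, 0.0261). With undetermined genes counted as having none, leukocyte markers lost theirs (42.9%, 0.0584), and NF-kB (88.5%, 0.0384) and TGF-beta (90.6%, 0.00776) gained one. With longer peaks, YAP/TEAD (87.5%, 0.0491), NF-kB (88%, 0.0491) and TGF-beta (87.5%, 0.0253) gained one. The first definition added NF-kB (92%, 0.0423) and TGF-beta (90.6%, 0.0323), and random lists of matched length added NF-kB (92%, 0.0203, from 10000 lists). Lists that turned direction never passed: mesenchymal with longer peaks (65.5%) and matched length (75.9%), luminal at any start (86.4%), with longer peaks (68.2%) and with undetermined genes counted as having none (68.2%), and WNT against matched length (75%).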

Other observations

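All tests in this part were chosen after the patterns were seen. Of the 2299 genes with no peak in the body or within 1000 bases of either end, 621 stood in 56 runs of at least 6 neighbouring protein-coding genes. The number of such runs that chance would give was not computed. Olfactory receptors led 13 runs and keratin-associated proteins 5. A run on chromosome 1 (12773738 to 13617957) held 28 genes, of which 22 belong to the PRAME family. A run on chromosome 4 held 22 genes, 19 of them USP17L genes, and a run on chromosome 5 held SMN1 and SMN2. Whether reads shared between near-identical genes account for such runs was not tested, so a run need not be inaccessible.

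The stretch of 4.18 Mb on chromosome 9 without a peak holds the interferon cluster, whose genes are silent in most cells. Reads shared between near-identical interferon genes could cover at most the 0.405 Mb that these genes span, and 3.77 Mb lay outside it. Silence of the genes cannot be told apart from other causes: 0 of the 8 genes outside the family had a start peak, but a stretch chosen for having no peak can hold none, so the binomial p of 3.09e-05 (one-sided) carries no weight. Loss of both copies in the cells may be the cause, and peaks alone leave it open for the same reason. The bound first written for it, a flank under 25.5 peaks per Mb (the median window of 51 divided by 2), was met by the right flank at 23, which by that bound counted against a loss. The bound was then judged wrong, because that flank has 3 genes and the 288 windows with as few had a median of 21.8 peaks per Mb; this comparison was added after the bound was met.

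On chromosome 6, 10 neighbouring histone genes (26216200 to 26273412) had no start peak. Outside the run, 50 of 68 histone genes (73.5%) had a peak within 1000 bases of an end, or 50 of 78 with the run included. Most histone genes thus had a peak nearby. The window reaches beyond the genes, and sequence identity within the run was not measured. Reads shared between near-identical genes of the run therefore stay open as a cause. Loss of both copies of the whole interval is argued against by 1 peak between its first and last gene; loss of part of it, or a difference in cell state, stays open and was not tested.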
